A study of Mus musculus with 6 samples.

How the data were processed

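Total RNA was isolated from peritoneal macrophages of LysMCre/Cre and KLF2∆/∆ mice (C57BL/6, 8 weeks old) and hybridised to Affymetrix mouse arrays, 3 arrays per genotype. Per the labels' protocols, mice received 2 ml of thioglycolate broth, an irritant that draws cells into the peritoneal cavity, and the cavity was emptied 72 h later. Cells attached to plates for 4 h, non-adherent cells were washed off, and the rest stood for a further 24 h before LPS at 100 ng/ml was given for 6 h. Biotin-labelled cRNA was made from 150 ng of RNA. The adherent cells were not sorted in any step the labels describe. The design text speaks of 3 mice per genotype and of pairs, but no label ties an array to 1 mouse or says that equal replicate numbers mark a pair, so p-values measure the spread between these arrays.

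The authors deposited log2 intensities, 1 value per probe set and array, and the submitters' processing notes name Affymetrix Expression Console and RMA (robust multi-array average, a background correction, quantile normalization and summary of probes). A second deposited table holds the same values as linear intensity, called an untransformed signal per the file headers, and its log2 values differed from the first by at most 5.1e-05. Versions, the summary level, any filter and the genome build are not given in the sources used here, nor are slide or scan dates, so batches of arrays were not tested. RMA makes the distributions of the arrays alike, so a shift shared by most genes would not be visible. RMA also compresses large ratios of dim probe sets, and a value near the lower end of the scale is not evidence of expression. No 2 arrays held identical values.

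Of 35557 probe sets, 6613 with the lowest identifiers, none of them in the annotation table, were treated as controls, which left 28944. Of these, 21789 name 1 gene in the platform annotation, 1621 name several and 5534 name none. Symbols were updated through gene identifiers to the RefSeq table of assembly GRCm38.p6, which matched 21698 of the probe sets naming 1 gene. That table served only for names and for which genes neighbour each other, and no coordinates are given because the build behind the arrays is not named. Each of 19938 genes was represented by its brightest single-gene probe set over all 6 arrays (999 genes had several). Genes whose mean lay below the 40th percentile of the non-control probe sets (log2 7.49) were left out, which left 12649 tested genes and removed 7289. Of the genes named as called, Prg4, Cxcl5, Adm, Mmp8, Klrk1, Cpa3, S100a9 and Ccl8 had 1 group mean under this level, so their changes are given as measured.

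Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, no replicate block), two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The prior added 15.4 degrees of freedom and the median standard error was 0.068. The number of arrays limits the precision. For Klf2 and Lyz2 an exact permutation test over the arrays was added. The gene lists, 34 in number with 724 genes of which 579 were tested (63 had no single-gene probe set and 82 lay below the filter; a gene in several lists counts once), were fixed before the data were examined. The 30 lists with at least 5 tested members were tested with camera (preset correlation 0.01), adjusted over these lists. Genes named in the text are Klf2 and Lyz2, the 10 largest rises and 10 largest falls past the threshold with no overlap between groups (predicted genes without a proper name were passed over), and up to 4 members of each list with the smallest p, or all called members where 5 or fewer were called. Any other gene is said to have been chosen after its values were seen.

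The test was tried on simulated data made from the real means and spread of these arrays, for the comparison of the arrays labelled KLF2∆/∆ with the LysMCre/Cre arrays over 12649 genes with 200 changed. It recovered 32.8% of 67 changes of 0.25 on the log2 scale, 80.6% of 67 changes of 0.5 and 100% of 66 changes of 1, with 3 false calls. With no change it made 0 calls. The simulated genes were drawn independently of each other, with the same spread in both groups. These counts therefore do not measure false calls among correlated genes, with unequal spread or with a batch that follows the groups. The real comparison called 3766 genes, and the adjustment is less strict where more genes change. The recovered shares therefore hold for 200 changed genes and do not give the sensitivity of the real comparison. Alternatives covered the replicate block, the scaling, array weights, the variance model, the filter, the probe sets of a gene, the test, the threshold, the set test and leaving out each array in turn. The closing section gives their effect. Figures were drawn with matplotlib 3.10.9.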

Results

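Gene expression was measured on 6 mouse arrays of thioglycolate-elicited peritoneal macrophages, all exposed to lipopolysaccharide (LPS, a bacterial cell wall component sensed by Toll-like receptor signalling) at 100 ng/ml for 6 h. Of these, 3 arrays carried the label LysMCre/Cre, in which the Cre recombinase sits in the lysozyme gene Lyz2 that myeloid cells express. The other 3 carried the label KLF2∆/∆, for mice with the same Cre and a floxed Klf2 gene. No untreated cells were analysed here, so the values compare the genotypes after LPS and do not measure the response to LPS. The median log2 intensity per array over the non-control probe sets lay between 7.85 and 7.90. Pearson's r across genes was 0.994 to 0.997 for pairs of arrays of the same group and 0.981 to 0.986 for pairs of different groups, and genes are not independent replicates. The first principal component held 72.6% of the variance and parted the groups, with scores of -13.1, -13.7 and -12.2 for the LysMCre/Cre arrays and 13.9, 11.3 and 13.8 for the others. The second held 10.5%, with scores of -8.75 and 8.29 for KLF2∆/∆ replicates 2 and 3 and of -0.62 to 0.80 for the LysMCre/Cre arrays. Mean r with the own group was 0.9971 to 0.9972 for LysMCre/Cre arrays and 0.9949 to 0.9955 for the others. The latter thus varied more, while the test pools the variance of both groups. Below, every change is the mean log2 intensity of the arrays labelled KLF2∆/∆ minus that of the LysMCre/Cre arrays, with n = 3 in each group, and adjusted p values are limma's unless another test is named.

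The deleted gene was read first. Klf2, a zinc finger transcription factor described as a repressor of proinflammatory activation in myeloid cells, gave log2 intensities of 8.88, 8.97 and 8.94 in the LysMCre/Cre arrays and 9.10, 9.25 and 9.21 in the arrays labelled KLF2∆/∆ (probe set 10572800). Its signal was therefore higher, not lower, in the arrays labelled as deleted, by 0.26 ± 0.064 (SE) or 1.20-fold, with limma adjusted p = 0.00398. The exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 can give. Without moderation of the variances adjusted p was 0.0522, in a range of 0.000662 to 0.0522 over 18 alternatives. This goes against the label, so each direction given here is a direction between arrays labelled one way and arrays labelled the other. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, and a probe outside that part would not check the label. Lyz2, which carries the Cre in both groups, had mean values of 10.25 ± 0.070 and 10.25 ± 0.072 (SD, n = 3) and a change of 0.0050 ± 0.057 (SE, adjusted p = 0.964, exact permutation p = 0.7).

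**Figure D1:**
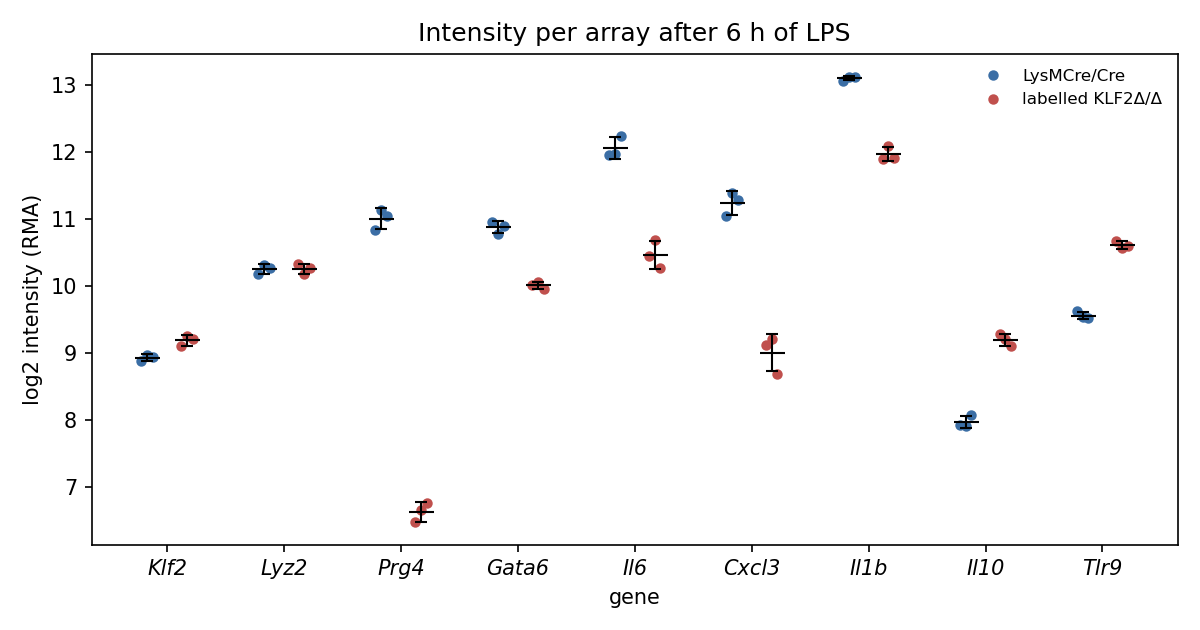
Log2 intensity (RMA) of 9 genes on each of the 6 arrays after 6 h of LPS, with points for single arrays, horizontal lines for group means and error bars for the SD (n = 3). Klf2 was higher by 0.26 in the arrays labelled KLF2∆/∆, Lyz2 differed by 0.0050, and Prg4 was lower by 4.37 as measured, to a mean under the intensity filter, with no overlap between the groups.

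The arrays labelled KLF2∆/∆ had lower signals for a set of inflammatory mediators, for markers of resident peritoneal macrophages, for stromal and mesothelial markers, and for cell cycle and cholesterol synthesis genes. Each of these lists lost its call with an estimated correlation (adjusted p of 0.0737 to 0.244). Signals were higher for Toll-like receptors and interferon-stimulated genes, lists that also lost their call with an estimated correlation (adjusted p = 0.244 for both), and for the anti-inflammatory cytokine Il10. The largest difference was in Prg4, the lubricating glycoprotein lubricin, at 11.00 ± 0.15 in LysMCre/Cre arrays and 6.63 ± 0.14 in arrays labelled KLF2∆/∆ (SD), where the lower mean lay under the intensity filter of 7.49 and is not told from background. Measured against that filter level, Prg4 was at least 11.4-fold lower (-3.51 on the log2 scale). Il6, a proinflammatory cytokine, was 3.01-fold lower and Il10 was 2.34-fold higher. Of 12649 genes tested, 3766 (29.8%) passed an adjusted p of 0.05, with 1723 higher and 2043 lower in the arrays labelled KLF2∆/∆. The balance turned after quantile normalization was applied again, with 2120 higher and 1961 lower, and with a filter at the 60th percentile, with 1690 higher and 1649 lower. Most of these changes were small: the median size among the called genes was 0.27, and the median change over all tested genes was 0.0019. A change of at least 2-fold was seen in 9 of the higher and 64 of the lower genes. Among all tested genes, 5156 (40.8%) had no overlap between the values of the groups, against 10% by chance for 3 arrays against 3.

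**Figure D2:**
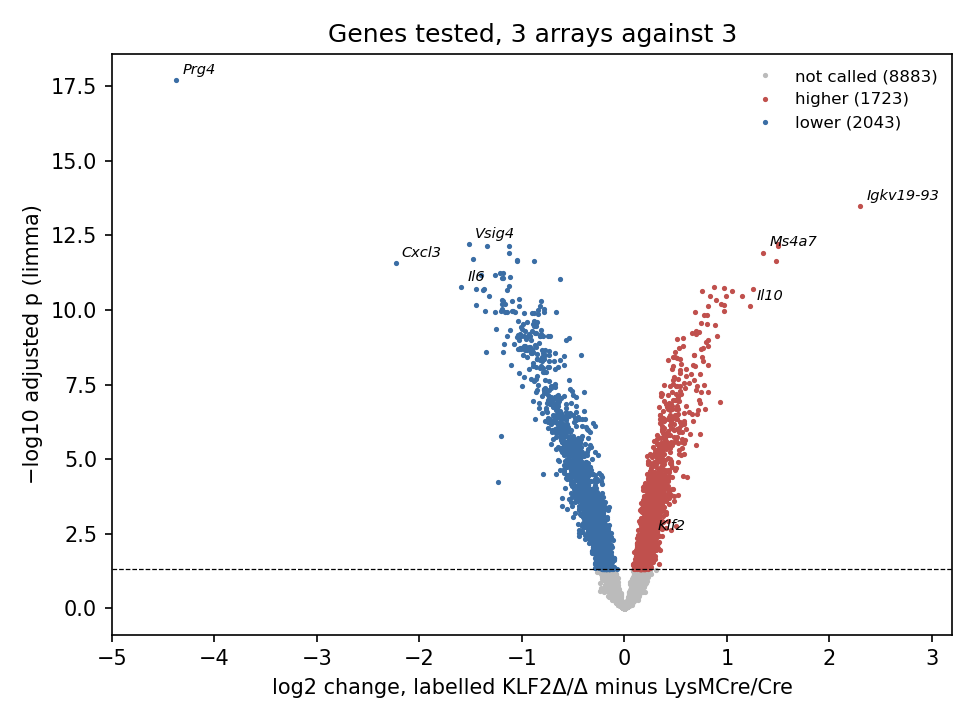
Each point is 1 of the 12649 tested genes, with the log2 change (arrays labelled KLF2∆/∆ minus LysMCre/Cre) on the x axis and -log10 of limma's adjusted p on the y axis, and a dashed line at an adjusted p of 0.05. The 1723 higher and 2043 lower genes are coloured, and Prg4 stands apart at a measured -4.37. After quantile normalization was applied again the counts were 2120 and 1961.

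Among the 10 largest rises were Igkv19-93, an immunoglobulin kappa variable segment from a family of similar sequences that probes can share (2.30 ± 0.074 SE, 4.92-fold, adjusted p = 3.23e-14; 1.12 with its probe sets averaged), and 2 membrane-spanning 4A family genes, Ms4a6b (2.82-fold) and Ms4a7 (2.55-fold). The C-type lectin gene Clec4a3 rose 2.82-fold. On the log2 scale, the VEGF receptor gene Kdr rose by 1.25, Il10 by 1.23 ± 0.071 (from 7.96 to 9.19, adjusted p = 7.45e-11) and the dicarboxylate transporter gene Slc13a3 by 1.15. The DNA sensor Tlr9 rose by 1.05, the transcriptional repressor Bcl6 by 0.99 and the carbonyl reductase gene Cbr2 by 0.98. The 10 largest falls were led by Prg4 (-4.37 ± 0.082 SE as measured, adjusted p = 2.00e-18), the neutrophil-attracting chemokine Cxcl3 (-2.23 ± 0.10, 4.70-fold) and Il6 (-1.59 ± 0.082, from 12.05 to 10.46, adjusted p = 1.75e-11). Next came the complement receptor Vsig4 (-1.52), the retinol dehydrogenase Rdh10 (-1.48), the chemokine Cxcl5 (-1.45 as measured) and the protease inhibitor Serpina3n (-1.45). With its lower mean held at the intensity filter, Cxcl5 changed by -0.93. The cytochrome P450 genes Cyp1b1 and Cyp7b1 changed by -1.40 and -1.38, and Arg1, the arginase of alternatively activated macrophages, by -1.37.

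Proinflammatory cytokines were lower as a group. Of 18 tested members, 14 fell, 3 rose and 1 did not pass, and the counts adjusted over the list alone were 14 and 3. Il1b changed by -1.13 (2.19-fold, adjusted p = 7.14e-13), Il33 by -1.26, Il1a by -0.67 and Il6 as above. Tnf, named after its values were seen because it was the member that did not pass, changed by -0.047 (adjusted p = 0.390) from a mean of 13.27. The list's median was -0.51, and the set test against all other genes gave adjusted p = 3.05e-09 (adjusted p = 0.244 with an estimated correlation). Chemokines went both ways. Of 25 tested, 14 fell, 4 rose and 7 did not pass, and adjusted over the list alone 15 fell and 5 rose. Beside Cxcl3 and Cxcl5, Cxcl13 changed by -1.15 and Cxcl2 by -0.54. Chosen after their values were seen, the neutrophil-attracting Cxcl1 changed by -1.35, the interferon-induced Cxcl9 and Cxcl11 by 0.50 and 0.70, and Ccl8 by 0.81, while Cxcl10 and Ccl5 changed by -0.036 and 0.0086 and did not pass (adjusted p = 0.383 and 0.871), Cxcl10 with the other sign after quantile normalization (0.0027). The chemokine median was -0.22, with set test adjusted p = 0.000318 (adjusted p = 0.244 with an estimated correlation). In the same arrays the fibroblast and mesothelial markers had a median change of -0.43 and the resident macrophage markers of -0.61. Without some of the members that those cells can also make (Il6, Il33, Cxcl1, Cxcl3, Cxcl5 and Cxcl13), a choice made after seeing the data, 12 of 16 cytokines fell and the list kept its call (median -0.46, adjusted p = 5.59e-07), but the chemokine list lost it (10 of 21 fell, median -0.10, adjusted p = 0.0750). Without Csf1, Csf3, Inhba and Lif as well, which stromal cells can also make and which were chosen after their values were seen, 8 of 12 cytokines fell and 3 rose (median -0.31, adjusted p = 0.000362; adjusted p = 0.258 with an estimated correlation).

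Receptors and adaptors that sense microbial products were higher, as were the other lists of this paragraph, in arrays whose fibroblast and mesothelial markers had a median of -0.43, resident macrophage markers of -0.61 and general macrophage markers of 0.068. Of 26 tested genes of Toll-like receptor sensing, 17 rose, 1 fell and 8 did not pass (adjusted over the list alone, 17 and 2), with a median of 0.19 and set test adjusted p = 1.97e-06 (adjusted p = 0.244 with an estimated correlation). Tlr9 rose by 1.05 (2.08-fold), the adaptor Ticam2 by 0.54, and the nucleic acid sensors Tlr13 and Tlr8 by 0.49 and 0.40. Chosen after their values were seen, Tlr4 and Tlr2 changed by -0.17 and 0.040 and did not pass (adjusted p = 0.0967 and 0.468). Interferon-stimulated genes shifted by a small amount in the same direction: 25 of 39 rose, none fell and 14 did not pass (adjusted over the list alone, 28 rose). The guanylate binding protein Gbp7 rose by 0.32, the antiviral synthetase Oas3 by 0.24, the signal transducer Stat2 by 0.22 and Ifit2 by 0.21. Their median was 0.14, with adjusted p = 9.47e-09 (adjusted p = 0.244 with an estimated correlation). In the list of NF-kB subunits, inhibitors and feedback genes, 9 of 26 rose, 1 fell and 16 did not pass (adjusted over the list alone, 10 and 1). The members that moved most clearly included inhibitors of the pathway, Tnip3 (0.76) and Nfkbie (0.37), the activation marker Cd83 (0.25) and, downwards, the stress gene Ier3 (-0.58). The list's median was 0.073 and its adjusted p 0.0201 (adjusted p = 0.345 with an estimated correlation). This call was lost with quantile normalization (adjusted p = 0.102) and with a stricter filter (adjusted p = 0.0502), in a range of 0.0102 to 0.102 over the 18 alternatives other than the estimated correlation. Co-activators and histone acetyltransferases that act at NF-kB promoters, a list that also holds co-repressors and deacetylases, were higher in 7 of 12 cases, lower in none, and did not pass in 5 (adjusted over the list alone, 8 and 1). Ncoa1 rose by 0.44, the acetyltransferase gene Ep300 by 0.34 and Ncoa3 and the deacetylase gene Sirt1 by 0.29 each, and the list had a median of 0.15 and adjusted p = 0.00363 (adjusted p = 0.345 with an estimated correlation).

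**Figure D3:**
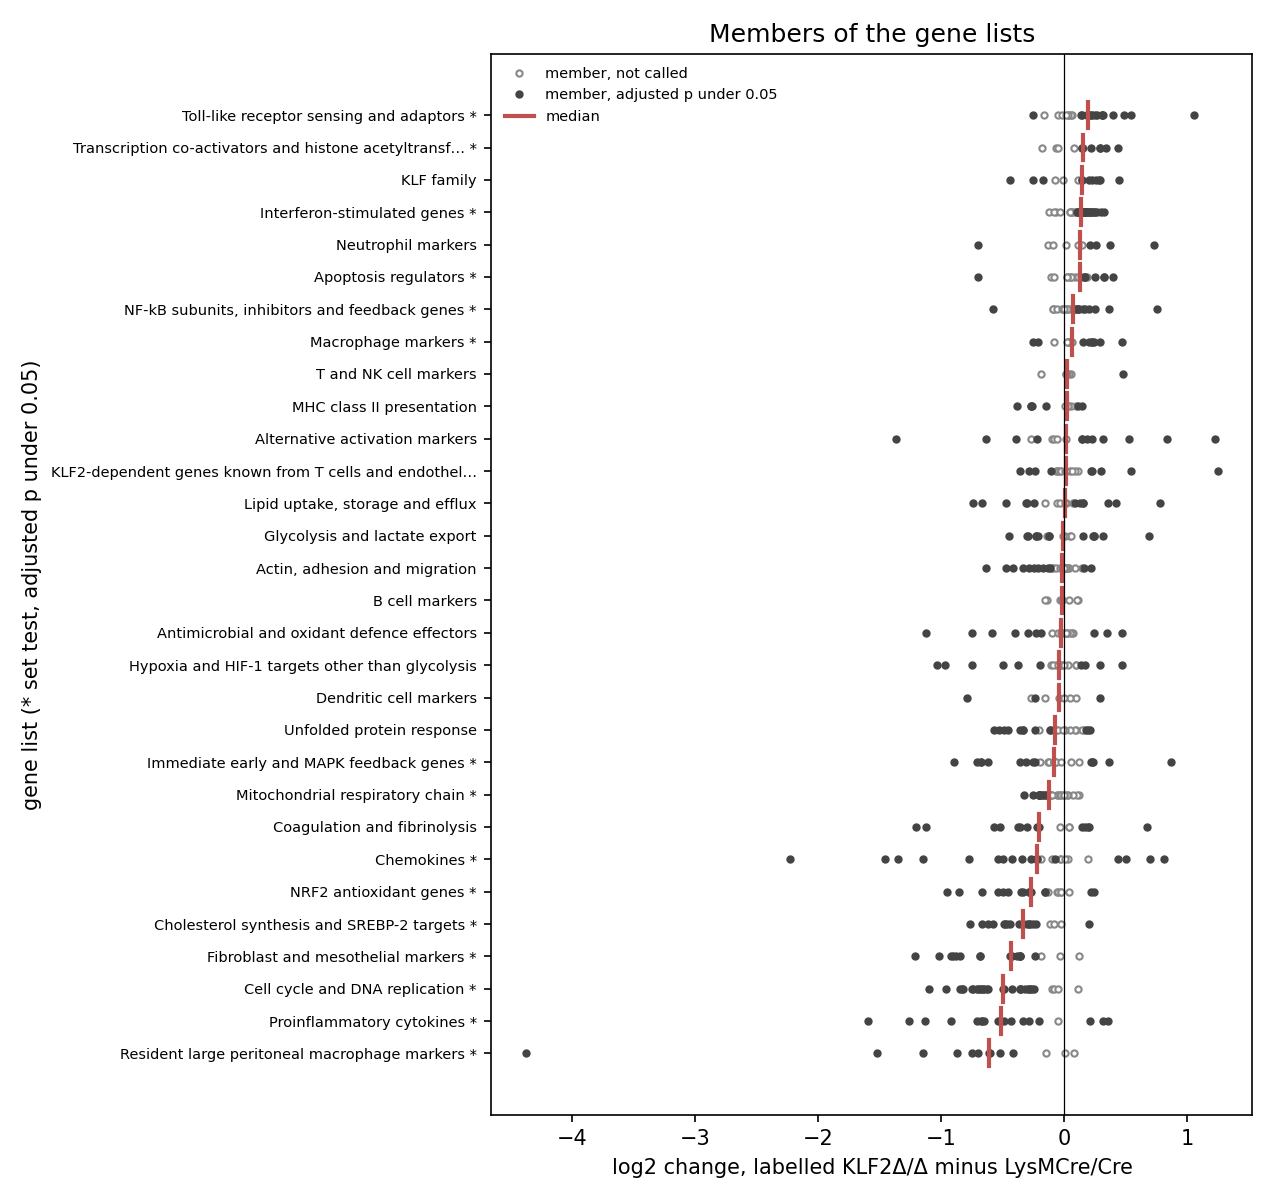
Log2 change (arrays labelled KLF2∆/∆ minus LysMCre/Cre, x axis) of each tested member of the 30 gene lists with a set test (y axis), with filled points for members past an adjusted p of 0.05, red bars for list medians and asterisks for lists called with a preset correlation. The medians ran from -0.61 for resident macrophage markers to 0.19 for Toll-like receptor sensing, and those of glycolysis (-0.0050), antimicrobial effectors (-0.024), lipid handling (0.012) and B cell markers (-0.015) took the other sign under another scaling.

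Markers of resident large peritoneal macrophages, the cells that hold the cavity before an irritant recruits monocytes, were lower: 10 of 13 fell, none rose and 3 did not pass (adjusted over the list alone, 11 fell). Apart from Prg4, Vsig4 and Cxcl13, the lineage transcription factor Gata6 changed by -0.87 (1.82-fold). The median was -0.61 and the set test adjusted p 2.04e-10 (adjusted p = 0.0737 with an estimated correlation). Fibroblast and mesothelial markers were also lower, with 15 of 18 falling, none rising and 3 not passing (adjusted over the list alone, 16 fell). The growth factor receptor Pdgfra changed by -1.21, the mesothelial gene Lrrn4 by -1.01, the matrix protein Sparc by -0.88 from a mean of 12.74, and the collagen gene Col1a2 by -0.85. Their median was -0.43, with adjusted p = 9.34e-13 (adjusted p = 0.229 with an estimated correlation). General macrophage markers were slightly higher, with 7 of 15 rising, 2 falling and 6 not passing (adjusted over the list alone, 7 and 2). The Fc receptor Fcgr1 rose by 0.47, the phagocytic receptor Mertk by 0.29, and the complement gene C1qb and the myeloid transcription factor Spi1 by 0.23 each, and the list had a median of 0.068 and adjusted p = 0.00622 (adjusted p = 0.244 with an estimated correlation).

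No list of another cell type was called by camera with a preset correlation, while the rotation test fry called the neutrophil (adjusted p = 0.0294) and dendritic cell (adjusted p = 0.00290) lists. Of 10 tested neutrophil markers 4 rose, Mmp8 (0.74), Csf3r (0.38), S100a9 (0.26) and Fcnb (0.21), and Chil1 fell (-0.70; adjusted over the list alone, 5 rose and 1 fell; set test adjusted p = 0.162). The calls of S100a9 and Fcnb were lost under 9 and 8 of 17 alternatives, over which adjusted p ran from 0.0201 to 0.274 and from 0.0149 to 0.137. For S100a9 these included quantile normalization (adjusted p = 0.0781), array weights (0.0810), no intensity trend (0.0557), no filter (0.0690) and all probe sets (0.0754), and its change was 0.14 without KLF2∆/∆ replicate 2. Among fits without single arrays, the calls lost were S100a9 without LysMCre/Cre replicates 1 and 2 and KLF2∆/∆ replicate 2 (adjusted p = 0.131, 0.103 and 0.227), Fcnb without LysMCre/Cre replicates 1, 2 and 3 and KLF2∆/∆ replicates 1 and 3 (0.123, 0.110, 0.0631, 0.0954 and 0.137). None of 8 B cell markers passed in either count (adjusted p = 0.902). Of 7 T and NK cell markers, Klrk1 rose (0.48; adjusted over the list alone also 1; adjusted p = 0.536). In the dendritic cell list, 1 of 9 rose (Tcf4, 0.29) and 2 fell (Fscn1, -0.79, and Ccr7, -0.23), with 3 falling and 1 rising when adjusted over the list alone (adjusted p = 0.320). Lists with fewer than 5 tested members had no set test. All 4 tested mast cell markers fell in both counts, Cpa3 (-0.52), Tpsb2 (-0.42), Hdc (-0.21) and Gata2 (-0.21), and with no intensity filter camera tested 11 and called the list lower (adjusted p = 0.0322). Hdc lost its call without LysMCre/Cre replicate 1 (adjusted p = 0.0505), and Gata2 without LysMCre/Cre replicates 1, 2 and 3 and KLF2∆/∆ replicates 1 and 2 (0.112, 0.152, 0.0517, 0.104 and 0.180, the last with a change of -0.14). Gata2 lost its call under 10 of 17 alternatives in all (0.00733 to 0.206), quantile normalization among them (0.0801). Of 4 eosinophil markers, Alox15, which resident macrophages also express, fell (-0.60), also when adjusted over the list alone. The 1 tested erythroid marker, Slc4a1, did not pass (-0.071) in either count. Of 3 tested Y-linked genes, 2 passed in both counts, Uty (0.24, adjusted p = 0.0195) and Eif2s3y (0.18, adjusted p = 0.0300), while Kdm5d changed by 0.0067. Uty lost its call without LysMCre/Cre replicate 1 and KLF2∆/∆ replicates 1 and 2 (adjusted p = 0.114, 0.0878 and 0.0640), and Eif2s3y without LysMCre/Cre replicates 1, 2 and 3 and KLF2∆/∆ replicate 2 (0.0525, 0.112, 0.0941 and 0.0979).

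Cell cycle genes were lower. Of 31 tested, 27 fell, none rose and 4 did not pass (adjusted over the list alone, 27 fell and 1 rose). The proliferation marker Mki67 changed by -1.10 (2.14-fold), the mitotic kinase Plk1 by -0.96, the cyclin Ccna2 by -0.85 and Cdk1 by -0.82. The median was -0.50 with adjusted p = 2.32e-16 (adjusted p = 0.182 with an estimated correlation), in arrays whose fibroblast and mesothelial markers had a median of -0.43. Immediate early and MAPK feedback genes split: 9 of 25 fell, 5 rose and 11 did not pass, with the same counts when adjusted over the list alone. The phosphatase gene Dusp1 rose by 0.87, while Myc changed by -0.89, the mRNA decay factor Zfp36l1 by -0.71 and Dusp6 by -0.68. The list had a median of -0.085 and adjusted p = 0.0411 (adjusted p = 0.345 with an estimated correlation). Apart from the estimated correlation, that call was lost under 4 of 18 alternatives, over which adjusted p ran from 0.00508 to 0.0605, among them the fits without LysMCre/Cre replicate 2 (0.0575) and without KLF2∆/∆ replicate 1 (0.0540).

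The lists of cholesterol synthesis, NRF2 antioxidant and respiratory chain genes were lower, in arrays whose fibroblast and mesothelial markers had a median of -0.43 and whose resident macrophage markers had one of -0.61. In cholesterol synthesis and its SREBP targets, 16 of 20 fell, 1 rose and 3 did not pass, with the same counts when adjusted over the list alone. Cyp51 changed by -0.76, the squalene epoxidase gene Sqle by -0.67, Hsd17b7 by -0.62 and the sterol sensor Insig1 by -0.44, and the list had a median of -0.33 and adjusted p = 3.76e-08 (adjusted p = 0.244 with an estimated correlation). Among NRF2 antioxidant genes, 13 of 21 fell, 2 rose and 6 did not pass, again with the same counts when adjusted over the list alone. The cystine transporter Slc7a11 changed by -0.95, Gstp1 by -0.85, the glutathione synthesis gene Gclm by -0.67 and Srxn1 by -0.53, with a median of -0.27 and adjusted p = 3.81e-05 (adjusted p = 0.289 with an estimated correlation). Of 31 mitochondrial respiratory chain genes, 8 fell in both counts, none rose and 23 did not pass, with Ndufa4 at -0.33, Cox4i1 at -0.25, Atp5c1 at -0.20 and Sdhc at -0.17. Their median was -0.12 and the set test adjusted p 0.0119 (adjusted p = 0.503 with an estimated correlation). Apart from the estimated correlation, the mitochondrial call was lost under 3 of 18 alternatives, over which adjusted p ran from 0.000994 to 0.0778, including the fit without KLF2∆/∆ replicate 3 (0.0544). Apoptosis regulators were higher in 6 of 20 cases, lower in 1 and did not pass in 13, in both counts. Casp1 rose by 0.39, Casp4 by 0.32 and Casp8 by 0.25, all caspases, while the death receptor Tnfrsf10b changed by -0.70, and the list had a median of 0.13 and adjusted p = 0.00887 (adjusted p = 0.345 with an estimated correlation).

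The 11 remaining lists held genes that moved in opposite directions and were not called by camera with a preset correlation, whose adjusted p is given for each, while fry called 9 of them (adjusted p of 0.00508 to 0.0252), all but glycolysis and lipid handling. For hypoxia and HIF targets, 6 of 20 fell and 4 rose in both counts, with the hypoxia-inducible factor Epas1 at -1.03, Egln3 at -0.97, Adm at -0.75 and Nos2 at 0.47 (adjusted p = 0.207). Chosen after their values were seen, Hif1a changed by -0.065 (adjusted p = 0.355) and Vegfa by -0.50 (adjusted p = 3.06e-06). In glycolysis, 8 of 19 fell and 6 rose (adjusted over the list alone, 9 and 6), with Pfkfb3 at 0.69, Hk3 at 0.31, Pfkl at -0.45 and Aldoa at -0.23 (adjusted p = 0.880). Antimicrobial and oxidant effectors fell in 7 of 21 cases and rose in 3, in both counts, with the protease inhibitor Slpi at -1.12, the arginine transporter Slc7a2 at -0.40 and the lysozyme Lyz1 at 0.35 (adjusted p = 0.184). Coagulation and fibrinolysis genes fell in 9 of 17 cases and rose in 5, in both counts, with tissue factor (F3) at -1.21, Serpinb2 at -1.12, Plaur at -0.37 and F13a1 at 0.68, where stromal markers had a median of -0.43 (adjusted p = 0.0750). Of 17 alternative activation markers, 8 rose and 4 fell (adjusted over the list alone, 8 and 6), with Il10 and the folate receptor Folr2 (0.83) rising, and Arg1 and Socs2 (-0.63) falling (adjusted p = 0.350).

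In the KLF family, 8 of 14 members rose, Klf2 included, and 3 fell, in both counts, with Klf13 at 0.45, Klf8 at 0.29, Klf7 at 0.20 and Klf9 at -0.44 (adjusted p = 0.0825). Among genes known to depend on KLF2 in T cells and endothelium, 5 of 20 rose and 4 fell in both counts, with Kdr at 1.25, Il7r at 0.55, Il6ra at 0.30 and Ccr7 at -0.23 (adjusted p = 0.287). For lipid uptake, storage and efflux, 7 of 20 rose and 6 fell (adjusted over the list alone, 8 and 7), with the oxysterol receptor Nr1h3 at 0.78, Pltp at 0.43, Plin2 at 0.35 and Olr1 at -0.74 (adjusted p = 0.669). Unfolded protein response genes fell in 9 of 25 cases and rose in 3 (adjusted over the list alone, 10 and 4), with the chaperones Hsp90b1 at -0.53, Hyou1 at -0.49 and Calr at -0.36, and Pdia4 at -0.57 (-0.32 with its probe sets averaged; list adjusted p = 0.0650). In MHC class II presentation, 5 of 12 fell and 2 rose in both counts, with H2-Ab1 at -0.38, H2-Aa and H2-Eb1 at -0.27 each and Cd74 at -0.26 (adjusted p = 0.276). Actin, adhesion and migration genes fell in 10 of 29 cases and rose in 2 (adjusted over the list alone, 10 and 3), with fibronectin (Fn1) at -0.63, Itgax at -0.47, Timp1 at -0.33 and Vcl at -0.29 (adjusted p = 0.0640). The coagulation list passed without LysMCre/Cre replicates 1 and 2 (adjusted p = 0.0286 and 0.0415), the unfolded protein response list without LysMCre/Cre replicate 2 and KLF2∆/∆ replicate 2 (0.0415 and 0.0497) and the actin list without LysMCre/Cre replicate 1 and KLF2∆/∆ replicate 2 (0.0286 and 0.0497). The actin list passed under 6 of the 18 alternatives other than the estimated correlation (adjusted p of 0.0144 to 0.129), among them quantile normalization (0.0188). Median, mean and test differed in sign in 3 lists: MHC class II (median 0.021, mean -0.070, test down), lipid handling (median 0.012, mean -0.039, test up) and B cell markers (median -0.015, mean -0.012, test up).

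With a preset correlation the set test called 15 of 30 lists, 6 higher and 9 lower. With an estimated correlation it called 0, against 5 at an unadjusted p under 0.05, and the rotation test fry, which asks only whether a list's genes move one way on balance, called 25. Among the called lists the estimated correlation ran from 0.0078 for resident macrophage markers to 0.39 for respiratory chain genes, against the preset 0.01. Every called list but the resident one lay above the preset. The resident list lost its call as well (camera adjusted p = 0.0737), so a larger correlation does not account for that loss. Of the genes named here, Casp1, Klf8, Klrk1, Ndufa4, Cox4i1, Atp5c1, Lif, Cxcl9 and Cxcl11 lost their call only without moderation of the variances (adjusted p of 0.0522 to 0.101).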

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

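Of the tests in this part, only those of stromal share by further markers, of scaling by centring and of the splits of arrays for gene lists were planned before their results were seen. Groups of 3 were not tested for outlying arrays, and a single comparison leaves no difference between effects to test.

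Probe sets outside the tested genes also changed. Of 1036 that name several genes, 92 were higher and 232 lower in the arrays labelled KLF2∆/∆ (31.3% called). Of 2495 with no gene in the annotation used, 215 were higher and 257 lower (18.9%). Among the 6613 probe sets treated as controls, 27 were higher and 40 lower (1.01%). These controls were fitted and adjusted apart with no intensity filter, so their share is not comparable with the shares above.

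Klf2 was higher, not lower, in the arrays labelled KLF2∆/∆. A single mislabelled array within the study is argued against, because 0 of the 6 arrays correlated better with the other group than with its own. An exchange of the labels of the groups as a whole may account for the direction. Klf2 stood at the 70.5th percentile of non-control probe sets in the arrays labelled LysMCre/Cre. That is no deletion to background either, but it does not decide the question, because the completeness of the deletion was not measured. Loss of a repressor of proinflammatory activation would raise proinflammatory cytokines, but 14 of 18 fell and 3 rose in the arrays labelled KLF2∆/∆. Toll-like receptor sensing (17 of 26 rose) and interferon-stimulated genes (25 of 39 rose) went the other way. These directions do not decide it, since stromal and resident macrophage markers differed too. Probes outside the deleted part of Klf2 could leave the signal in place, and it stood at the 74.9th percentile in the arrays labelled KLF2∆/∆. These explanations, a batch that follows the groups, and a true rise of a remaining transcript cannot be told apart, because probe positions and array dates are not given in the sources used here.

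Stromal, mesothelial and resident macrophage markers were lower in the arrays labelled KLF2∆/∆, beside lower Il6 and Cxcl3. A smaller share of stromal and mesothelial cells among the adherent, unsorted cells is a candidate explanation: of 14 further markers with a mean log2 intensity of at least 9, taken from a list written before the test, 13 (92.9%) were lower, among them Igfbp7 (-0.79 from 12.20) and Acta2 (-0.81 from 11.53), and Cav1, named like these after its values were seen, was higher (0.14, adjusted p = 0.0377, lost under 10 of 18 alternatives with a range of 0.0191 to 0.267, the highest without LysMCre/Cre replicate 1). Scaling that depends on intensity is argued against, since members of the first stromal list changed by a median of -0.42 (95% interval by signed ranks -0.74 to -0.35) relative to the 100 tested genes outside the lists nearest in intensity, while centring each array on its median, which left that list at -0.43, moved every gene alike by 0.0068 and decides nothing. That share as the whole cause of the falls of Il6 and Cxcl3 stays open. Il6 fell by 0.38 ± 0.10 (SE) and Cxcl3 by 1.02 ± 0.12 more than Pdgfra, the marker of the first list with the largest fall. These SEs treat the genes as independent, although they were measured on the same arrays. With the filter level taken off as background, however, 4 of 44 stromal markers fell as much as Il6 or more (Upk1b, also named after its values were seen, by 1.76 against 1.73). These 4 include markers with means near that level (7.57 and 7.79). Only 1 marker fell as much as Cxcl3 (2.74) or more, and it ended under that level. For Prg4, taken up as the largest fall, the change minus that of Gata6 was -3.51 ± 0.10 (SE, the genes taken as independent) as measured. It was at most -2.64 with Prg4 held at the intensity filter, and the other called markers had a median of -0.70. This argues against a smaller share of resident macrophages alone only if those markers come from resident macrophages alone. A marker that other cells also make would fall by less than the share, and its source was not tested in these unsorted cells. A change within the stromal or resident cells, a partial effect of their shares, a batch that follows the groups and the genotype as a biological cause stay open.

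The arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 3766 genes and the highest of the other splits called 0 with limma (111 to 379 at an unadjusted p under 0.05), and 1 of the 10 splits, the real one, reached its count. For gene lists the real split called 15 and the highest other split called 9. Those calls of up to 9 lists with no gene called were made by the set test with a preset correlation, and their cause was not tested. Every other split puts arrays of both groups on each side, so the difference between the groups adds to the spread within sides. That holds down gene calls in those splits, and their sides still hold the groups in unequal shares. The counts of the other splits therefore do not measure what chance alone would call.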

How the results depend on the processing

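No called list and no named gene that was called, Klf2 included, changed direction under the 26 alternative settings that gave it a value, of which 2, testing inflammatory lists without members that other cells can make, were chosen after seeing the data. Of 19 named genes that were not called, 6 took the other sign in at least 1 setting, of which 2 did so under another scaling, Cxcl10 and Prg3. Tlr2 and Tlr4 are in neither this count nor the next. Of 170 genes besides Klf2, 148 kept their side of the threshold in every setting, 16 lost a call in at least 1 (9 of these only with the unmoderated test) and 6 gained one. Of all main calls, 2 of 3742 changed sign when the probe sets of a gene were averaged. Without moderation of the variances 2124 genes passed, 969 higher and 1155 lower, and 2003 of the 3766 main calls kept theirs; Klf2 then stayed at 0.26 with adjusted p = 0.0522, in a range of 0.000662 to 0.0522 over 18 alternatives. A threshold of at least 2-fold left 73 genes, 9 higher and 64 lower, both with an adjusted and with an unadjusted p under 0.05. The second condition lowers the count by construction, while for the unmoderated test, 121 of whose calls were not main calls, the cause was not tested. Leaving out each array in turn gave 2935 to 3776 genes, 1312 to 1849 higher and 1623 to 2278 lower, a Klf2 change of 0.23 to 0.31, 11 to 14 gene lists and 3 cell type lists each time. With an estimated correlation 0 of the 12 gene lists and 0 of the 3 cell type lists called with a preset one passed (5 of 30 at an unadjusted p under 0.05), and with fry 20 and 5 lists did. The preset and the estimated correlation are settings of the same test, so the calls depend on that setting, while fry asks a different question of the same values. The mean correlation within groups exceeded that between groups by 0.0125, and by 0.00519 with no filter; the cause was not tested. Quantile normalization moved the split of calls to 2120 higher and 1961 lower, and a filter at the 60th percentile moved it to 1690 and 1649. Another scaling moved the median of all genes by at most 0.019.

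Arrays with equal replicate numbers showed no common sign: their deviations from the group means correlated at -0.091, 0.12 and -0.049, and 2 of 6 arrays correlated best with their own number. LysMCre/Cre replicate 3 with KLF2∆/∆ replicate 1 gave 0.18, and LysMCre/Cre replicate 1 with KLF2∆/∆ replicate 3 gave 0.087. Deviations within a group depend on each other, so these values do not decide whether arrays pair by number or in another order. With the number as a block 3824 genes passed, 1747 higher and 2077 lower, 3688 of the 3766 main calls among them, and the coagulation (adjusted p = 0.0353) and unfolded protein response (0.0482) lists gained a call. Over the 18 alternatives other than the estimated correlation, coagulation ranged from 0.00884 to 0.318 and the unfolded protein response from 0.0158 to 0.136, and with an estimated correlation both had adjusted p = 0.503. Signal over background limits what the arrays can show for the 7289 genes under the filter.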

Other observations

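The tests of gene families, and all genes named from them here and in the next paragraph, were chosen after the values were seen, while the test of DNA flanking Klf2 was planned before. Families of genes that share a symbol stem gave further groups: of 409 families tested with camera, 7 were lower and 4 higher in the arrays labelled KLF2∆/∆, and with an estimated correlation 0 passed (lowest adjusted p = 0.997). In the same arrays the fibroblast and mesothelial markers had a median of -0.43 and the resident macrophage markers of -0.61. Of 33 genes with the stem Rpl, which large-subunit ribosomal proteins carry, 20 fell and none rose (median -0.14, adjusted p = 0.000467). Of 29 with the stem Rps, which small-subunit proteins share with S6 kinases and other genes, 13 fell and none rose (median -0.13, adjusted p = 0.00371), although the S6 kinase gene Rps6kb2 (0.15, adjusted p = 0.0580) passed as higher after quantile normalization (adjusted p = 0.0160). Rpl5 changed by -0.39 and Rps18 by -0.37. Of 8 genes with the stem Nop, 6 fell (median -0.36, adjusted p = 0.0363), with Nop56 at -0.48 and Nop16 at -0.50, as did 11 of 17 box C/D small nucleolar RNAs (Snord, median -0.25, adjusted p = 0.00258) and 8 of 14 box H/ACA ones (Snora, median -0.19, adjusted p = 0.0169). The chaperonin subunits (Cct) fell in 6 of 7 cases (adjusted p = 0.00764), with Cct3 at -0.44.

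Of 54 genes with the stem Rab, which Rab GTPases share with proteins that bind them, 19 rose, 1 fell and 34 did not pass (median 0.073, adjusted p = 0.0186), with Rab7b at 0.93 and Rab31 at 0.44. Of 13 syntaxin genes (Stx) 7 rose and none fell (median 0.14, adjusted p = 0.0336), with Stx2 at 0.38 and Stx11 at 0.34. Of 9 genes with the stem Slfn, which Schlafen genes share with an antisense transcript and a pseudogene, 3 rose and none fell (adjusted p = 0.0423), with Slfn4 at 0.39. The median of none of these 11 families changed sign when the arrays were quantile normalized again or centred on their medians. Counts of called members did move. After quantile normalization 20 Rpl, 16 Rps and 5 Snora genes fell and 8 Stx genes rose. After centring 15 Rpl, 10 Rps and 5 Snora genes fell and 5 Stx genes rose. The set test of families was not run again under these scalings. The remaining families called, counted among the 11, were the Toll-like receptors (7 of 9 rose, adjusted p = 0.00258) and the insulin-like growth factor binding proteins (Igfbp, 4 of 5 fell, adjusted p = 0.00421), of which Igfbp7 and Igfbp4 are also among the further stromal markers.

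DNA flanking the modified Klf2 allele may differ between the groups and change genes near Klf2. Among the 50 tested genes on each side of Klf2, 2 of 100 (2%, exact 95% interval 0.243 to 7.04) were called with a change over 0.5 on the log2 scale, against 4.46% elsewhere (one-sided Fisher's exact p = 0.940). The share was not higher near Klf2, but its interval reaches above 1.5 times the share elsewhere, so a small excess stays open.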
